A study of Caulobacter vibrioides NA1000 with 10 samples.

How the data were processed

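The series measured chromosomal occupancy by CtrA, the DNA-binding response regulator that directs the Caulobacter crescentus cell cycle, by chromatin immunoprecipitation and sequencing (ChIP-seq) in strain NA1000 and mutants. Per the labels' protocols, cultures grew in PYE, a rich peptone and yeast extract medium, at 30 °C. Cells were crosslinked with 1% formaldehyde for 10 min. DNA was sheared to 0.3 to 0.5 kbp and CtrA was precipitated with a polyclonal rabbit antibody at a dilution of 1 in 1000. The series holds 10 samples: 9 ChIP libraries, each the only library of its group, and 1 wild-type input library. The title of the input has the code prefix AIYT and no growth phase. Which control each peak call used is not given in the sources used here. A peak list for each of the 9 ChIP libraries was used here. The growth protocol in the labels gives mid-log phase (optical density 0.5 at 660 nm) for every sample, whereas the titles of 3 samples say stationary phase. The phase was taken from the titles.

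Reads were processed with CASAVA 1.8.2, Bowtie and MACS2 2.1.1.20160309.6, per the submitters' processing notes. The Bowtie version and the genome build are not given in the sources used here. Peaks were called per library at a q-value limit of 0.05, per the file headers. The headers of the mutant lists keep the words for wild-type CtrA, and 1 file name combines both growth phases where its title says exponential. Each list was therefore assigned by the library code in its header, which matched exactly 1 title. The pileup is a coverage signal at the summit as deposited by the authors. It holds whole numbers in 7 lists and scaled values in the rpoB* exp and ptsP spoT rpoB* exp lists. The significance columns are the −log10 p-value and −log10 q-value deposited by the authors. The fold enrichment is the authors' own ratio of pileup to local background for each summit. It was used to describe, rank or filter sites within a list. Folds of different lists printed side by side are the deposited values and measure no difference in occupancy. Ranks were compared between 2 lists only over the same set of sites. Read totals are not given in the sources used here, so the read depth is unknown. The background that the authors' pileup and fold enrichment imply, (pileup + 1)/fold − 1, had a median between 707 and 1230 per list.

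A peak was a unique start and end. Rows that share an interval were summits of 1 peak, and a peak took the fold of its highest summit. Coordinates are 1-based as the files give them, on a chromosome that the peaks cover up to position 4042929. A peak was called shared when it overlapped a peak of the other list over at least 50% of the shorter of the pair. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. The chance level is the mean share over 1000 circular shifts of 1 list along the chromosome. With 1 library per group no test between groups is possible and no p-value is given. Of the 12 comparisons, 8 set libraries with the same code prefix in their titles (GHA or AIYT) side by side. The other 4, each of WT exp against an AIYT library, cross prefixes, and there prefix and genotype cannot be told apart.

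Gene names came from a RefSeq gene table of assembly ASM2200v1 with 3886 protein-coding genes, used only for names and neighbourhood. The match of coordinates was checked on the data. Between 48.5% and 84.5% of the 200 highest-fold summits of a list lay between genes at an offset of 0. The mean at offsets of 500 bp or more was between 9.42% and 11.6%, and 9.58% of the chromosome lies between genes. The share was highest within 10 bp of an offset of 0 in all 9 lists. The table used gives no strand, so the planned promoter window (300 bp upstream to 100 bp downstream of the gene start) was applied to both gene ends. A site in this window is called beside the gene. A peak found in 1 list alone is that interval, and the other list may hold another summit beside the same gene. A gene with a summit in 1 list alone may have a summit of the other list just outside its window. The planned count of CtrA motifs at summits needs a genome sequence and was not run. The planned use of the authors' gene column was not run either, because the columns used here hold none.

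Before the data were examined, 9 gene lists were fixed: cell cycle regulators, cell division, flagellum and motility, chemotaxis, pili, holdfast and capsule, replication and chromosome, stringent response and phosphotransferase system (PTS), and ribosomal proteins. Of 147 fixed symbols outside the ribosomal list, 116 matched the gene table. The 31 without a match included 16 of the 19 chemotaxis symbols and rpoB, which is therefore not analysed here. Counts of members with a summit stand beside 10000 random lists of the same size. The rule for named genes was also fixed in advance. For each comparison it takes fixed-list members with a summit in only 1 library (at most 12, highest fold first). It adds the genes at the 6 highest-fold unshared peaks of either list and at the 5 highest-fold shared peaks. The genes ctrA, pilA, hvyA, sciP, fliL, fliQ, ccrM, gcrA, spoT and ptsP are reported whatever their values, and the text names a selection of these genes. Sites beside clpP, clpX, cpaA, dnaA, divJ, flgB, fljM, ftsZ, gyrB, perP, rcdA and tacA are named for their ranks, and the sites of the closing section outside this rule for their library sets, after their values were seen.

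Ranks were an analysis added after seeing the data. A site entered a comparison when its summits in the 2 lists were each other's nearest and within 100 bp. Sites were ranked in each list by the authors' fold enrichment, with rank 1 the highest. The shift is the difference in percentile rank, in points. For a named gene with several sites, the one ranked highest in the first list was used, while medians of gene lists take every site beside a member. For a named site, the share of like sites (those in the same of 10 classes by mean rank) that moved at least as far in the same direction is given as a description. The median shift of a gene list stands beside 10000 random lists of sites with the same size and mean rank. Where stated, these were also matched on side, the origin-proximal or terminus-proximal 50% of the chromosome, but not on position within it. Such percentiles were computed for 87 pairs of list and comparison with at least 5 sites. Neighbouring sites of 1 operon are not independent. Overlap functions were tested on simulated lists. At true shares of 30%, 60% and 90% the error was 0 points over 10 simulated pairs of lists with 1200 peaks in the first. The simulated peaks were kept apart, so this result follows by construction and does not measure accuracy on crowded lists. Joint losses set by fold alone gave 1.01 times the redrawn number. Rank shifts were tested on the 2812 WT exp summits with 50 simulated lists of 20 sites. Lists moved by 20 points gave a mean of 19.7 points and all 50 lay outside the middle 95% of random lists, as did 2 of 50 lists that were not moved. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.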

Results

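CtrA occupancy was mapped in 9 ChIP-seq libraries of Caulobacter crescentus NA1000, a bacterium that alternates between a motile swarmer cell and a stalked cell. Exponential cultures gave 6 of them: wild type (WT exp), the allele ctrA401 with the substitution T170I (ctrA401 exp), ctrA401SS, which carries T168I beside T170I (ctrA401SS exp), an rpoB mutant written rpoB* (rpoB* exp), the ptsP spoT double mutant (ptsP spoT exp) and its rpoB* derivative (ptsP spoT rpoB* exp). Stationary cultures gave wild type (WT stat), the spoT mutant (spoT stat) and the ptsP mutant (ptsP stat). SpoT makes and degrades the alarmone (p)ppGpp, and PtsP is enzyme I of the nitrogen-related phosphotransferase system. Each group had 1 library, so no difference given here could be set against replicate error. The authors' peak calls numbered 1915 in WT exp, 1088 in ctrA401 exp, 1198 in ctrA401SS exp, 2045 in WT stat, 1891 in spoT stat, 1840 in ptsP stat, 1268 in rpoB* exp, 1233 in ptsP spoT exp and 1307 in ptsP spoT rpoB* exp. With a fold enrichment of at least 2 the order was another, with 242 peaks in WT exp, 369 in ctrA401 exp and 516 in ctrA401SS exp. All peaks together covered between 15.1% of the chromosome in ctrA401 exp and 28.9% in WT stat. The read depth is unknown, and the background pileup implied by the authors' values had a median between 707 in WT stat and 1230 in rpoB* exp.

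The site of highest fold in 5 of the lists lay between CCNA_01125 and CCNA_03890 (1231158 to 1231731 in WT exp), with a fold enrichment of 20.0 in WT exp, 11.8 in WT stat, 16.7 in ptsP spoT exp and 26.1 in rpoB* exp. The promoter region of ctrA, the gene of the regulator itself, held a summit at 3279720 with a fold of 5.81 in WT exp, and between 3279695 and 3279731 in the other lists. Sites beside pilA (the major pilin), hvyA (an inhibitor of capsule formation), sciP (a small protein that inhibits CtrA), fliL and fliQ (flagellar genes) and ccrM (an adenine DNA methyltransferase) were found in all 9 lists. Cell cycle regulators had a summit beside 20 to 25 of 26 members, against a mean of 11.0 to 15.6 in random gene lists. Flagellar genes had one beside 21 to 31 of 33 members, against a mean of 14.0 to 19.9, and ribosomal protein genes beside 23 to 26 of 26, against 11.0 to 15.7. The lowest flagellar count, 21 in ctrA401SS exp, was reached by 5.84% of random lists. All ribosomal members but rplS and rpsU lie in 1 gene cluster from rpsJ to rplQ and often share a summit. Random lists draw scattered genes, so the ribosomal counts, and the ribosomal rank shifts below, largely describe 1 locus. Among the 200 highest-fold summits of each list, however, ribosomal genes had 0 to 3 members, flagellar genes 11 to 19 and cell cycle regulators 6 to 11. Members with any summit numbered 8 to 11 of 13 for cell division, 5 to 7 of 12 for pili and 7 to 10 of 14 for holdfast and capsule. They numbered 8 to 11 of 11 for replication, 6 to 7 of 7 for the stringent response and PTS, and 1 to 3 of 3 for chemotaxis. Random lists averaged 5.49 to 7.82 members for cell division, and 46.6% of them reached the count of spoT stat and 35.5% that of WT stat. They averaged 5.1 to 7.2 for pili, 5.9 to 8.4 for holdfast and capsule, 4.67 to 6.62 for replication, 2.98 to 4.23 for the stringent response and PTS, and 1.3 to 1.8 for chemotaxis.

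The peaks at spoT and ptsP went with the labels as far as peak lists can show it. No summit lay inside spoT in the spoT stat, ptsP spoT exp and ptsP spoT rpoB* exp lists, where peaks covered 0%, 1.21% and 0% of the gene. The other 6 lists had 5.79% to 35.7% of spoT under peaks, although ctrA401 exp also had no summit inside it. Peaks covered 0% of ptsP in ptsP stat, 2.43% in ptsP spoT exp and 1.72% in ptsP spoT rpoB* exp, against 3.09% to 8.65% in the other 6 lists. No list had a summit inside ptsP, so these values cannot show a deletion.

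**Figure D1:**
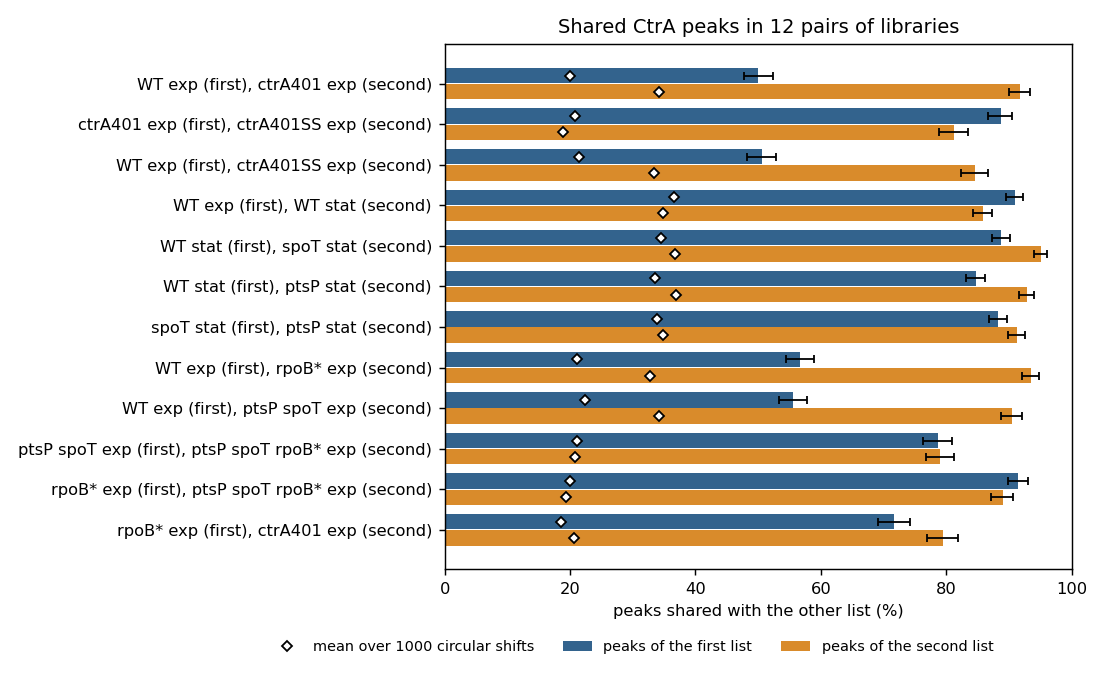
Bars give the percentage of peaks shared with the other list (x axis, 0 to 100%) for 12 pairs of libraries (y axis), in blue for the first list and orange for the second, with exact 95% intervals for counting error and diamonds for the mean of 1000 circular shifts. The lowest bar is 50.03% (WT exp with ctrA401 exp) and the highest 95.1% (spoT stat with WT stat), and all bars lie above their diamonds.

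The comparison of WT exp with ctrA401 exp asks where CtrA sits when it carries T170I. The hvyA site ranked 39 of the 1171 sites found in both lists in WT exp and 166 in ctrA401 exp. A lower rank in ctrA401 exp was also seen for sciP (37 and 182), fljM, a flagellin gene (38 and 188), and tacA, a transcription activator of stalk formation (155 and 595). Of the sites with a similar mean rank, 3.39% moved as far down as hvyA, 1.69% as far as sciP, 0.847% as far as fljM and 0.855% as far as tacA. In contrast, ctrA ranked 14 in WT exp and 4 in ctrA401 exp, ftsZ, the cytokinetic tubulin, 53 and 6, and cpaA, a pilus assembly gene, 92 and 33, moves that 40.7%, 16.1% and 11.0% of similar sites matched. The pilA peak was in both lists, but its main summit lay at 3198806 in WT exp and 134 bp away at 3198940 in ctrA401 exp, and the other 7 lists had it within 50 bp of the WT exp position. At sciP the highest summit was at 1026365 (fold 3.97) in WT exp and at 1026912 (fold 3.94) in ctrA401 exp. WT exp also had a summit at 1026899 (fold 1.98) and ctrA401 exp one at 1026318 (fold 3.13). Both lists thus held summits near both positions. Cell cycle regulators as a list had a median shift of 4.36 percentile points toward ctrA401 exp, with 18 of 24 sites ranked higher there, above 99.0% of random lists. The 5 holdfast and capsule sites had a median of 11.5 points (4 of them higher), above 99.7% of random lists. Ribosomal protein sites had 9.35 points (18 of 20 higher), above 97.97% of random lists, but above 72.6% when these were also matched on side, that is, on the numbers of sites in the origin-proximal and terminus-proximal 50% of the chromosome. Fixed genes with a summit in only 1 of the lists numbered 11 in WT exp and 7 in ctrA401 exp. The latter included ftsW, a division gene, with a fold of 9.78 (2787316 to 2787711, between ftsW and CCNA_02636), dksA with 2.24, cpaJ, a pilus gene, with 2.11, rplP, a ribosomal protein gene, with 1.86, and pleD, a diguanylate cyclase gene, with 1.60. In WT exp only, cheD had 1.54 and spoT 1.37.

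Of the WT exp peaks, 50.03% (958 of 1915, exact 95% interval 47.8 to 52.3) were shared with ctrA401 exp, where circular shifts gave 20.0%. Of the ctrA401 exp peaks, 91.7% (89.9 to 93.3) were shared, against 34.2%. The unshared WT exp peaks were weak, with a median fold of 1.31 against 1.67 for the shared ones, and 4 of them reached a fold of 2. Among peaks with a fold of at least 2 in both lists the share was 83.9% of 242 in WT exp and 55.6% of 369 in ctrA401 exp. Among equal numbers of highest-fold peaks it was 75.5% of WT exp. The highest unshared WT exp peak lay between CCNA_00155 and CCNA_00156 (164175 to 165483, fold 2.69). These libraries carry different code prefixes, so genotype and library set cannot be told apart here.

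**Figure D2:**
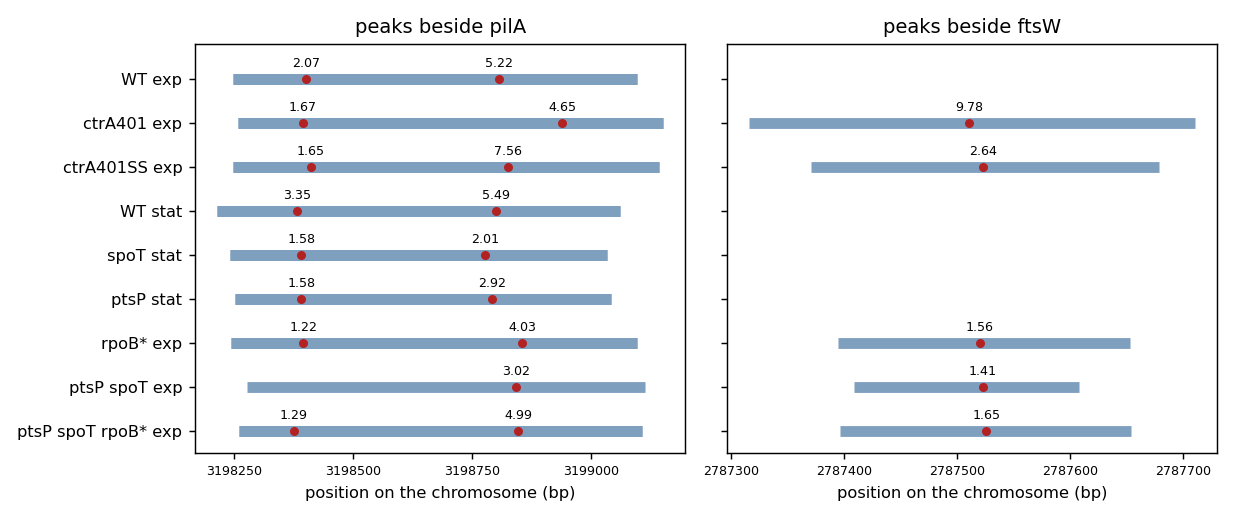
Peaks (bars) and summits (dots, with the authors' fold enrichment) in the 9 libraries (y axis) beside pilA and ftsW, by position on the chromosome in bp (x axis). The main pilA summit of ctrA401 exp lies at 3198940, away from those of the other lists near 3198806, and peaks beside ftsW are found in 5 lists, with folds from 1.41 to 9.78.

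The second substitution was examined by setting ctrA401 exp beside ctrA401SS exp. The cpaA site ranked 33 of 1210 in ctrA401 exp and 499 in ctrA401SS exp, and the ftsW site 34 and 387. Of sites with a similar mean rank, 1.65% and 0.826% moved as far down. The fljM site ranked 193 and 64 (4.13% as far up), while hvyA (167 and 163), ccrM (41 and 62) and ctrA (4 and 6) held nearby ranks. The main pilA summit of ctrA401SS exp was 19 bp from that of WT exp, with a fold of 7.56. All 22 ribosomal protein sites ranked lower in ctrA401SS exp, with a median shift of -25.8 points, below every random list matched on rank and side. All but 1 of these sites lie in the cluster from rpsJ to rplQ, so this is largely 1 locus and not 22 independent sites. Flagellar sites had a median of -5.45 points (17 of 24 lower), with 3.32% of random lists below it. Fixed genes with a summit in ctrA401SS exp alone numbered 6, among them hfsJ, a holdfast synthesis gene (2.37), pleC, a histidine kinase gene (1.83), and zapA (1.57). Those in ctrA401 exp alone numbered 8, which were the ribosomal protein genes rpmC (2.44), rplX (2.11) and rplS (1.78) and 5 flagellar genes, among them fliG (1.34). The rpmC summit of ctrA401 exp (1436511) had a ctrA401SS exp summit within 100 bp of it, at 1436584 (2.69), outside the rpmC window. The peak of highest fold in ctrA401 exp alone lay between CCNA_00804 and yihA (868708 to 869111, fold 5.99), followed by one between CCNA_03719 and gltD, a glutamate synthase gene (3884823 to 3885286, fold 4.46). In ctrA401SS exp alone it lay between CCNA_02060 and CCNA_02061 (2209920 to 2210583, fold 5.13). The lists shared 88.7% of the peaks of ctrA401 exp (86.7 to 90.5, against 20.8% by shifts) and 81.2% of ctrA401SS exp (78.9 to 83.4, against 18.9%).

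Against WT exp, ctrA401SS exp had lower ranks for cpaA (94 and 425 of 1088) and tacA (155 and 608), where 3.67% and 1.83% of similar sites moved as far. The ranks of hvyA were 40 and 146, of sciP 38 and 145, and of pilA 17 and 49, but 11.0%, 10.1% and 28.4% of similar sites moved as far. Ribosomal protein sites, nearly all in 1 cluster, had a median shift of -12.4 points (10 of 17 lower). Of random lists 4.76% lay below, and 0.1% when matched on side. Cell cycle regulators had 3.77 points (17 of 24 higher), above 96.4% of random lists. Peaks in ctrA401SS exp and not in WT exp reached a fold of 7.31 beside CCNA_02604 and CCNA_02605 (2749346 to 2750521), 5.78 beside pbp1A, a penicillin-binding protein gene (1702051 to 1702413), 5.36 beside glk, the glucokinase gene, and 4.15 beside clpB, a chaperone gene. Fixed genes with a summit in 1 of these lists numbered 16 in WT exp, 3 of them ribosomal (rpmC, rplX and rplS), and 10 in ctrA401SS exp, with ftsW (2.64), pleD (2.51), dksA (2.49) and rplP (1.83). Of the WT exp peaks 50.5% (48.3 to 52.8) were shared, against 21.4% by shifts, and 84.6% (82.4 to 86.6) of those of ctrA401SS exp, against 33.4%. Among peaks with a fold of at least 2 in both lists the share was 90.1% of 242 in WT exp and 43.2% of 516 in ctrA401SS exp. The prefixes differ in this pair too.

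Growth phase in the wild type was compared within 1 code prefix. The site between cckN and divJ, both histidine kinase genes, ranked 834 of 2319 in WT exp and 39 in WT stat, and 0.431% of similar sites moved as far up. The sciP site ranked 39 and 3, perP, a protease gene, 176 and 52, and gcrA, an S-phase regulator gene, 512 and 177, with 25.4%, 9.48% and 6.03% of similar sites as far up. The dnaA site, at the gene of the replication initiator, ranked 134 and 302 (3.45% of similar sites moved as far down), and gyrB, a gyrase gene, 526 and 1356 (5.60%). The sites of pilA (18 and 18) and ccrM (37 and 36) held their ranks. The 12 sites of the replication list had a median shift of -20.4 points (9 lower) and the 10 of the stringent response and PTS list -18.9 points (6 lower and 4 higher), with 0.05% and 0.03% of random lists below. Ribosomal protein sites, most of them in the 1 cluster from rpsJ to rplQ, had -14.1 points (15 of 19 lower), with 0.02% below. Matching random lists on side as well, which leaves the distance from the origin within a side unmatched, gave 0.12%, 0.08% and 0%. A summit beside hfsJ (106145 to 106460, fold 2.95) and one beside dksA (1.68) were in WT stat alone. Peaks between CCNA_00350 and CCNA_00351 (365857 to 366183, fold 3.59), beside hfsK, a holdfast synthesis gene (2.62), beside cpdR, whose product is a proteolysis adaptor (842156 to 842447, fold 2.18), and beside kidO, a division inhibitor gene (2.01), were in WT exp alone. Other summits beside cpdR (1.95) and kidO (1.42) were in WT stat. Shared peaks made up 90.9% of WT exp (89.5 to 92.2, against 36.6% by shifts) and 85.9% of WT stat (84.3 to 87.3, against 34.9%). With a fold of at least 2 required in both lists, the share was 55.0% of 242 in WT exp and 82.2% of 163 in WT stat.

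**Figure D3:**
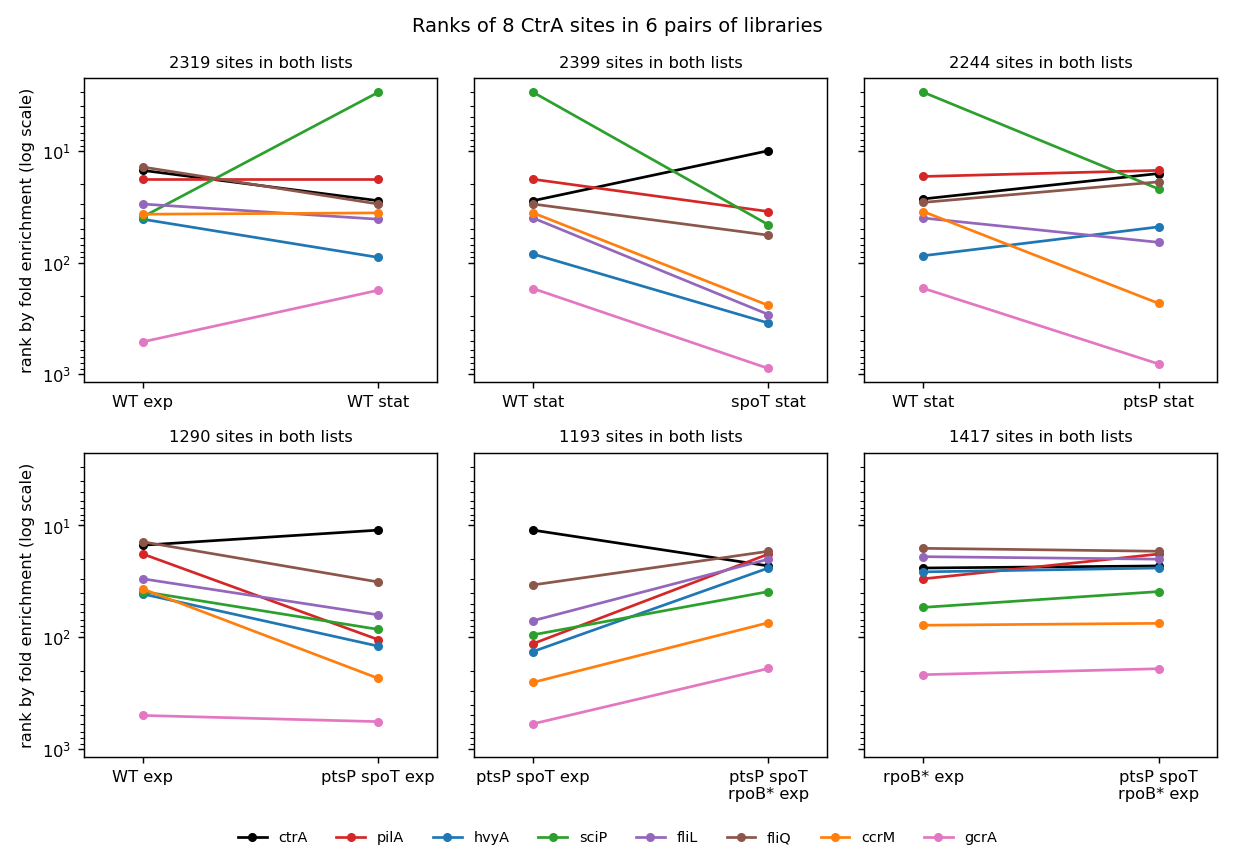
Ranks of 8 named sites by the authors' fold enrichment (y axis, log scale, rank 1 at the top) in 6 pairs of libraries (x axis), over the sites found in both lists of a pair. The ccrM site goes from 36 in WT stat to 242 in spoT stat and from 37 in WT exp to 233 in ptsP spoT exp, and it ranks 78 and 75 in the rpoB* exp and ptsP spoT rpoB* exp pair.

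Loss of spoT in stationary phase was set against WT stat. The ccrM site ranked 36 of 2399 in WT stat and 242 in spoT stat, fliL 40 and 292, hvyA 84 and 348, and perP 49 and 370. Of similar sites, 5%, 3.75%, 3.33% and 1.67% moved as far down. The gcrA site ranked 171 and 887, and tacA 183 and 978, with 6.25% and 4.58% as far down. The site beside ptsP ranked 119 and 2139, a shift that 0.833% of similar sites matched. In contrast, ctrA ranked 28 and 10 and pilA 18 and 35. Cell cycle regulators had a median shift of -6.04 points, with 15 of 23 sites lower in spoT stat and 0.04% of random lists below. The lists also differed in the highest-fold summits used to check the coordinates. Of these, 48.5% lay between genes in spoT stat and 70.5% in WT stat. Whether the rank shifts follow from a weaker enrichment of the whole spoT stat list was not tested. Summits between cckN and divJ (1220010 to 1220555, fold 4.15) and between fliX and flgI, flagellar genes (2818459 to 2818806, fold 3.58), were in WT stat and not in spoT stat. So were those beside hfsJ (2.95) and ftsN, a division gene (1.36). Fixed genes in 1 list only numbered 9 in WT stat and 6 in spoT stat, the latter with the ribosomal protein genes rplX (1.49), rplC (1.43) and rplW (1.42). The rplW summit of spoT stat (1433274) had a counterpart at 1433256 in WT stat, outside the rplW window. Of the WT stat peaks 88.8% (87.3 to 90.1, against 34.4%) were shared, and of the spoT stat peaks 95.1% (94.0 to 96.0, against 36.8%). The highest fold in spoT stat was 3.21 against 11.8 in WT stat, and 33 against 163 peaks reached a fold of 2. With that fold required in both lists, the share was 20.9% in WT stat and 100% in spoT stat, so the number of such peaks in spoT stat limits the lower value. Of the 100 highest-fold peaks of WT stat 57 were shared.

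In ptsP stat the ccrM site ranked 232 of 2244 against 35 in WT stat, gcrA 808 against 170, and divJ 196 against 38, shifts matched by 4.89%, 5.33% and 5.78% of similar sites. The hvyA site ranked 48 against 87, pilA 15 against 17, ctrA 16 against 27 and fliL 66 against 40. The 6 pili sites had a median shift of -9.51 points (4 lower), with 0.60% of random lists below, and 3.67% when matched on side. The 8 sites of the stringent response and PTS list moved the other way, by a median of 7.06 points (5 higher). That was above 97.5% of random lists, and 98.96% when matched on side. The peak of highest fold in WT stat alone lay between CCNA_00542 and CCNA_00543 (561508 to 561882, fold 7.99). Others lay between CCNA_03083 and CCNA_03084 (3.43), beside hfsJ (2.95) and beside nrdE, a ribonucleotide reductase gene (2.73). The ptsP stat list alone had a peak beside hfaA, a holdfast attachment gene (1.38), and a second one beside cpdR (1.45), where both lists had another summit (1.95 in WT stat and 1.60 in ptsP stat). The lists shared 84.7% of the peaks of WT stat (83.1 to 86.2, against 33.6%) and 92.8% of ptsP stat (91.6 to 94.0, against 36.8%). With a fold of at least 2 in both lists, the share was 47.9% of 163 in WT stat and 98.7% of 79 in ptsP stat.

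The direct comparison of both stationary mutants placed the hvyA site at 342 of 2240 in spoT stat and 49 in ptsP stat, perP at 364 and 85, fliL at 290 and 69, and tacA at 956 and 316. Of similar sites, 0.446%, 0.893%, 1.79% and 1.79% moved as far up. The ccrM site held 244 and 235, and ctrA 10 and 16. Among cell cycle regulators 22 of 26 sites ranked higher in ptsP stat, with a median shift of 3.84 points, above 99.1% of random lists. Of the highest-fold summits used to check the coordinates, 48.5% lay between genes in spoT stat and 63% in ptsP stat. Whether the rank shifts follow from this difference between the lists was not tested. Summits beside divJ (1.75), hfaA (1.38) and fliX and flgI (1.36) were in ptsP stat alone. Shared peaks made up 88.3% of spoT stat (86.7 to 89.7, against 33.9%) and 91.2% of ptsP stat (89.9 to 92.5, against 34.9%), and no unshared peak of either list reached a fold of 2.

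**Figure D4:**
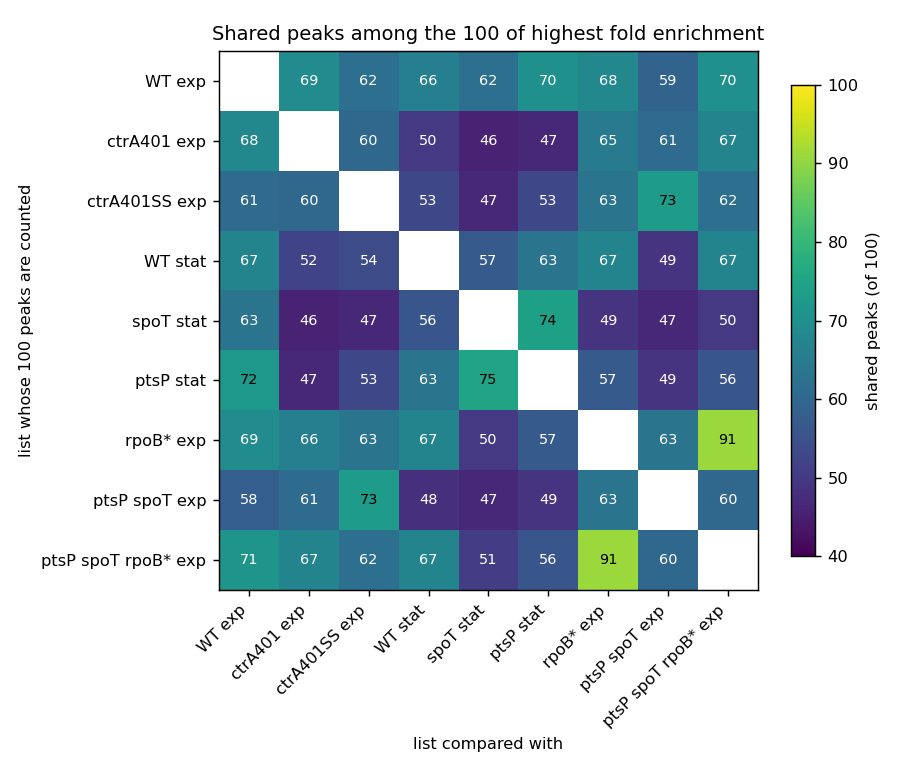
Number of shared peaks among the 100 of highest fold for every pair of the 9 libraries, with the list whose peaks are counted on the y axis and the list compared on the x axis (colour scale 40 to 100). The pair of rpoB* exp and ptsP spoT rpoB* exp has 91, spoT stat and ptsP stat 74, and ctrA401 exp and spoT stat 46.

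In exponential phase, rpoB* exp and WT exp had close ranks at most of the sites reported throughout. The hvyA site ranked 41 of 1309 in WT exp and 26 in rpoB* exp, fliL 30 and 19, fliQ 14 and 16, pilA 18 and 30, and ccrM 37 and 78. The dnaA site ranked 140 and 426, with 3.05% of similar sites as far down, and gcrA 502 and 207 (11.5% as far up). The 7 replication sites had a median shift of -21.8 points (5 lower), with 1.36% of random lists below. Fixed genes with a summit in 1 list only numbered 16 in WT exp and 10 in rpoB* exp, all with folds under 2, among them ftsW (1.56) and dksA (1.51) in rpoB* exp and rplX (1.90), divL (1.44) and chpT (1.42), the last 2 of them phosphorelay genes, in WT exp. The rplX summit of WT exp (1437154) had a paired summit at 1437056 in rpoB* exp, outside the rplX window. That site ranked 351 in WT exp and 266 in rpoB* exp, so it was present in both lists. Of the WT exp peaks 56.6% (54.4 to 58.8, against 21.2%) were shared, none of the unshared ones with a fold of 2 or more, and of the rpoB* exp peaks 93.5% (92.0 to 94.8, against 32.8%). Code prefix and genotype coincide in this comparison and in the next one.

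In ptsP spoT exp the ccrM site ranked 233 of 1290 against 37 in WT exp, and 0.775% of similar sites moved as far down. The tacA site ranked 662 against 159 (2.33% of similar sites), cpaA 341 against 95 (6.98%), hvyA 120 against 41 (17.8%) and pilA 105 against 18 (14.0%). The ctrA site ranked 11 against 15. Peaks in ptsP spoT exp and not in WT exp lay beside CCNA_02604 and CCNA_02605 (3.88), glk (3.12), pbp1A (2.93) and clpB (2.30). Of the fixed genes, dksA (1.96), pleD (1.79), rplP (1.48) and ftsW (1.41) were among 7 with a summit in ptsP spoT exp alone, and 12 had one in WT exp alone. Of the WT exp peaks 55.5% (53.3 to 57.8, against 22.4%) and of the ptsP spoT exp peaks 90.5% (88.7 to 92.1, against 34.2%) were shared.

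The effect of rpoB* on the double mutant was compared within 1 code prefix. Ranks of 1193 sites were higher in ptsP spoT rpoB* exp for tacA (692 and 147), hvyA (134 and 24), pilA (114 and 18), gcrA (594 and 190), ccrM (253 and 74) and cpaA (368 and 98). Of similar sites, 2.5%, 4.17%, 6.67%, 5%, 12.6% and 4.20% moved as far up. The dnaA site ranked 141 in ptsP spoT exp and 394 with rpoB* (5.88% as far down), and ctrA 11 and 23. Flagellar sites ranked higher with rpoB* at 22 of 26, with a median shift of 4.40 points, above 97.2% of random lists. Ribosomal protein sites ranked lower at 17 of 21, with a median of -4.86 points and 4.95% of random lists below. Replication sites ranked lower at 4 of 7, with a median of -13.2 points and 4.49% below. A summit between nudC and dnaX, a DNA polymerase III subunit gene (2.00), and one beside pleD (1.79) were in ptsP spoT exp alone, and one beside hfsJ (106179 to 106411, fold 1.48) with rpoB* alone. Fixed genes in 1 list only numbered 11 in ptsP spoT exp and 6 in ptsP spoT rpoB* exp, with 1 ribosomal protein gene in each. Shared peaks made up 78.7% of ptsP spoT exp (76.3 to 80.9, against 21.1%) and 79.0% of ptsP spoT rpoB* exp (76.7 to 81.2, against 20.8%). With a fold of at least 2 in both lists, the share was 45.4% of 282 in ptsP spoT exp and 83.9% of 155 in ptsP spoT rpoB* exp.

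The lists of rpoB* exp and ptsP spoT rpoB* exp were the most alike of the 12 pairs in rank, with a Spearman rho of 0.924 over 1417 sites. The sites of ccrM (78 and 75), hvyA (26 and 24), fliL (19 and 20), fliQ (16 and 17) and ctrA (24 and 23) ranked almost equally. The pilA site ranked 30 and 18, sciP 54 and 39, and ptsP 127 and 213. Ribosomal protein sites ranked lower in ptsP spoT rpoB* exp at 18 of 21, by a median of -4.45 points, with 0.09% of random lists below. Most of these sites lie in the 1 cluster from rpsJ to rplQ. Fixed genes with a summit in rpoB* exp alone numbered 5, with folds of at most 1.29 (pleD), and rplX (1.56) was the only one in ptsP spoT rpoB* exp alone. The lists shared 91.5% of the peaks of rpoB* exp (89.8 to 93.0, against 20.0%) and 89.0% of ptsP spoT rpoB* exp (87.2 to 90.6, against 19.4%), and no unshared peak had a fold of 2. These are different strains, so their likeness is a yardstick for the other pairs and not a replicate error. They are also the only lists with scaled pileup values, with the same median background of 1230, so the yardstick may not hold for other pairs. For the other 11 comparisons rho lay between 0.576 (WT exp and ctrA401SS exp) and 0.873 (WT stat and spoT stat).

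Set against rpoB* exp, which has the same prefix, ctrA401 exp had lower ranks for hvyA (24 and 166 of 1064), sciP (51 and 184), tacA (167 and 610) and pilA (28 and 96). Of similar sites, 0.935%, 2.80%, 1.89% and 8.41% moved as far down. The pilA pair joins the rpoB* exp summit at 3198856 with the displaced ctrA401 exp summit at 3198940, so its ranks may belong to different sites. The dnaA site ranked 427 in rpoB* exp and 91 in ctrA401 exp, ftsZ 53 and 6, flgB, a flagellar rod gene, 27 and 7, and ctrA 22 and 4, with 1.87%, 16.8%, 34.6% and 36.4% of similar sites as far up. Cell division sites ranked higher in ctrA401 exp at 8 of 9, by a median of 10.5 points, above 99.5% of random lists, and replication sites at 6 of 8, by 22.8 points, above 99.8%. Against WT exp, replication sites moved by 1.96 points in ctrA401 exp and -21.8 in rpoB* exp, and cell division sites by 3.07 and -6.26. The dnaA site ranked 91 in ctrA401 exp against 135 in WT exp, and 426 in rpoB* exp against 140. These shifts therefore cannot be credited to ctrA401 exp alone, and the pairs with WT exp cross code prefixes. Peaks in ctrA401 exp alone reached a fold of 6.59 beside hfsI, and those in rpoB* exp alone 2.47 beside hsp33, a chaperone gene. Summits beside cpaJ (2.11), dnaX (2.07) and chpT (2.06) were in ctrA401 exp alone. Shared peaks made up 71.7% of rpoB* exp (69.1 to 74.2, against 18.5%) and 79.5% of ctrA401 exp (76.98 to 81.9, against 20.6%).

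Of the 1915 WT exp peaks, 858 were missing from both ctrA401 exp and ctrA401SS exp, and 739 from both rpoB* exp and ptsP spoT rpoB* exp. Losses redrawn at random among peaks of like fold gave means of 669 and 488, and independent losses 473 and 350. The observed number was 1.14 to 1.51 times the redrawn mean over all 10 pairs of mutants, highest for rpoB* exp with ptsP spoT rpoB* exp. All pairs share WT exp as the reference and the same prefix in both mutants, so part of the excess may come from them.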

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

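The rank comparisons of this part were all chosen only after the peak lists had been seen. The rpoB* mutation was present or absent in 2 backgrounds, wild type and ptsP spoT, and 4 of 9 sites reported throughout moved in opposite directions in the ranking with rpoB*. These differences were not tested, because each list comes from 1 library, and the wild-type background also crosses code prefixes. Over the 936 sites found in all 4 lists, the ccrM site ranked 37 in WT exp, 77 in rpoB* exp, 228 in ptsP spoT exp and 74 in ptsP spoT rpoB* exp. Its shift with rpoB* was -4.27 percentile points in wild type and 16.5 in ptsP spoT, a difference of 20.7 points. The pilA site ranked 18, 30, 103 and 18, with shifts of -1.28 and 9.08 points and a difference of 10.4 points. The sciP site ranked 39, 53, 84 and 39, with a difference of 6.30 points, and fliQ 14, 16, 32 and 17, with a difference of 1.82 points. Opposite shifts were common among other sites too, at 459 of the 936 sites (49.0%) and at 39 of the 87 fixed genes with such a site. Groups of 1 library allow no search for outlying samples.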

How the results depend on the processing

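The 200 highest-fold summits were an alternative chosen after seeing the data, as were the 100 highest-fold peaks for pairs outside the 12 comparisons, a fold of at least 2 for the origin-proximal share, and the rank analyses. All other alternatives for the values below, among them the 100 highest-fold peaks in the 12 comparisons, were set before the data were examined. No paired analysis was possible because each group has 1 library. The planned CtrA motif count and the authors' gene column were not run. Of the alternative values for the peak numbers, shares, joint losses and fixed genes, 84 stayed within the error or ratio set for them and 84 moved. Any overlap of 1 bp, the wider promoter window, overlap of the whole peak with the window and another number of fold classes for joint losses moved none of these. Joint losses kept a ratio above 1 in every alternative run, up to 1.71 with the stricter q-value. Peaks with a fold of at least 2 numbered 242 in WT exp, 369 in ctrA401 exp, 516 in ctrA401SS exp, 163 in WT stat, 33 in spoT stat, 79 in ptsP stat, 133 in rpoB* exp, 282 in ptsP spoT exp and 155 in ptsP spoT rpoB* exp. That rule reverses the order of WT exp and ctrA401 exp. Fixed genes outside the ribosomal list beside the 200 highest-fold summits numbered 42, 41, 36, 46, 31, 34, 42, 33 and 42 in the same order of libraries, fewer by construction.

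The shares of the first list that moved are given in the order in which the report takes the 12 comparisons. With 50% of both peaks required to overlap, they were 35.9%, 80.1%, 34.7%, 81.4%, 81.2%, 74.9%, 80.5%, 42.3%, 40.3%, 67.2%, 86.4% and 58.4%. With summits within 100 bp, they were 41.7%, 81.2%, 38.7%, 82.6%, 80.9%, 75.8%, 79.4%, 46.6%, 46.0%, 70.1%, 85.7% and 64.3%. The first rule is stricter by construction, and the second counts summits and not peaks. With a fold of at least 2 in both lists, they were 83.9%, 91.9%, 90.1%, 55.0%, 20.9%, 47.9%, 97.0%, 45.0%, 70.7%, 45.4%, 96.2% and 89.5%. These shares are limited by the unequal numbers of such peaks, as in WT stat with spoT stat, where 100% of the spoT stat peaks were shared. With a −log10 q of at least 10 in both lists, 9 shares moved. They were 91.6% for ctrA401 exp with ctrA401SS exp, 53.8% for WT exp with ctrA401SS exp, 86.0% for WT exp with WT stat, 80.1% for WT stat with spoT stat, 74.8% for WT stat with ptsP stat, 82.3% for spoT stat with ptsP stat, 45.7% for WT exp with rpoB* exp, 69.6% for ptsP spoT exp with ptsP spoT rpoB* exp and 82.2% for rpoB* exp with ctrA401 exp. With equal numbers of highest-fold peaks, the moved shares were 75.5%, 83.5%, 68.9%, 87.5%, 92.0% and 89.7% for the first 6 comparisons. They were 71.5% for WT exp with rpoB* exp, 75.4% for WT exp with ptsP spoT exp, 76.2% for ptsP spoT exp with ptsP spoT rpoB* exp and 78.7% for rpoB* exp with ctrA401 exp. Of the 100 highest-fold peaks, the moved shares were 69, 60, 62, 66, 57, 63, 74, 68, 59 and 60 for the first 10 comparisons and 66 for rpoB* exp with ctrA401 exp. The cause of the moves was not tested beyond these rules. Values for single gene lists and for the origin-proximal share moved in 89 cases and stayed in 244. Fold enrichment differs between libraries, and with an unknown read depth a site missing from a list was only not detected in it.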

Other observations

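The test of depth in this part was chosen only after the results were seen, and the rank comparisons were added after seeing the data. Sites beside the genes of the ClpXP protease, which degrades CtrA, were compared in the ranking between growth phases. The clpX site ranked 173 of 2319 in WT exp and 14 in WT stat, and clpP 52 and 623. Of sites with a similar mean rank, 6.03% moved as far up as clpX and 0.862% as far down as clpP. The clpP summit lay at 2186905 in WT exp but at 2186809 in WT stat, just within the 100 bp limit. In the other lists it lay between 2186895 and 2186914, so the clpP ranks may belong to different sites. The clpX site ranked 8 of 1088 in ctrA401SS exp against 173 in WT exp, and 31 of 1290 in ptsP spoT exp against 178, moves that 0.917% and 0.775% of similar sites matched. It also ranked 68 of 1171 in ctrA401 exp against 174 (4.24%) and 57 of 1309 in rpoB* exp against 180 (3.82%). All of these pairs of mutant and WT exp cross code prefixes, whereas WT exp and WT stat have the same prefix. WT exp is the common reference of all these pairs. Its clpX summit lay at 2185164, against 2185179 in spoT stat and 2185210 to 2185231 in the rest. The rise therefore cannot be credited to a genotype or to the prefix. The rcdA site, at the gene of an adaptor for CtrA proteolysis, ranked 32 in WT exp and 79 in WT stat, and 30 and 29 of 1171 in WT exp and ctrA401 exp. These genes were named after their values were seen.

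The holdfast synthesis gene hfsJ had a summit in 4 lists, with folds of 2.95 in WT stat, 2.37 in ctrA401SS exp, 1.48 in ptsP spoT rpoB* exp and 1.33 in rpoB* exp, and none in the other 5. By contrast hfiA, which encodes a holdfast inhibitor, had a summit in all 9 lists, with folds from 2.30 in spoT stat to 22.4 in ctrA401 exp. Of the 9 lists, 5 carry the code prefix AIYT, and 11 peaks of ctrA401 exp were in all 5 of these and in no list with the prefix GHA. They lay beside ftsW (9.78 in ctrA401 exp), between CCNA_00221 and CCNA_00222 (3.76), between CCNA_00300 and CCNA_00301 (3.13), beside popZ, the gene of a polar organiser (1.81), beside glk (1.43) and between hfsB and hfsA (1.40), among others. All 4 stationary or wild-type lists have the GHA prefix, so genotype and library set cannot be told apart for these peaks.

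The origin-proximal 50% of the chromosome held 49.97% of peaks in WT exp (47.7 to 52.2) and 43.2% in WT stat (41.02 to 45.4), and it held 49.6% in ptsP spoT exp (46.8 to 52.5) and 40.1% in rpoB* exp (37.4 to 42.8). Among peaks with a fold of at least 2, a rule chosen after seeing the data, it held 62.4% (55.97 to 68.5), 54.0% (46.02 to 61.8), 52.5% (46.5 to 58.4) and 51.9% (43.1 to 60.6) in the same order, so intervals overlap within each pair. Each of these pairs lies within 1 code prefix. A copy number from origin to terminus that differs between the ChIP library and its control may account for this. It would raise the local background more often near the origin, and move strong sites up near the terminus and down near the origin. In WT exp the implied background lay above its list's lowest value at 81.5% of origin-side and 12.8% of terminus-side summits. In WT stat these were 78.9% and 13.4%, so this sign was present in both lists. It was present in all 9 lists, with 73.8% and 11.2% in ptsP spoT exp and 64.0% and 8.96% in rpoB* exp. It thus appeared whatever the share of origin-proximal peaks and decides nothing. From WT exp to WT stat, the 200 strongest shared sites moved down on both sides, by medians of -0.345 points near the terminus and -1.47 near the origin, a difference of 1.12 points (bootstrap interval over sites 0.561 to 1.81, with no error between libraries). For ptsP spoT exp and rpoB* exp the medians were -1.61 and -2.72, with a difference of 1.10 points (-3.14 to 3.74). Sites taken from the top of the first list tend to fall in the second whatever the cause, so the missing rise near the terminus decides nothing. The difference between the sides had the predicted sign for WT exp and WT stat, while the interval of the other pair spans both signs. Copy number and a difference in CtrA binding itself cannot be told apart for either pair, because each list comes from 1 library.

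The 4 GHA lists held 1840 to 2045 peaks and the 5 AIYT lists 1088 to 1307. With a fold of at least 2 they held 33 to 242 and 133 to 516, so the excess lay among weaker peaks. Depth in favour of GHA is argued against by the background pileup, whose highest GHA median was 917 and lowest AIYT median 1024, a ratio of 0.895. The pileup reflects reads and fragment length together, so it is no read count. The only input library has the prefix AIYT, and the control used for each list is unknown. The prefix may stand for another library or antibody preparation, but 3 of the 4 GHA lists are stationary, the other one (WT exp, 1915 peaks) is the only exponential wild-type list, and no genotype of the ChIP libraries appears under both prefixes, so genotype and prefix remain confounded.

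In WT exp 279 peaks were found in all 4 GHA lists and in no AIYT list, with a median fold of 1.28. The highest lay inside CCNA_00456 (465627 to 465920, fold 1.69). These peaks may be weak sites of the common kind that fell below the threshold elsewhere. Of them 86.7% (82.2 to 90.5) had their summit inside a gene, against 81.7% (76.7 to 86.1) of 279 peaks of like fold that were also in an AIYT list. The difference of 5.02 points lies within overlapping intervals. The matched peaks differed in other ways, since the origin-proximal 50% held 35.1% of the GHA peaks (29.5 to 41.0) and 13.3% of the matched ones (9.51 to 17.8), with median lengths of 318 and 385 bp. Weak common sites and sites specific to the GHA libraries therefore cannot be told apart with this matching.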
